A study of Bos taurus with 6 samples.

How the data were processed

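ChIP-seq libraries of H3K4me3 and H3K27me3 from 2 independent lines of bovine embryonic stem cells, A and B, gave 1 list of peaks each, 4 lists in all. Chromatin was made with a micro-ChIP kit after the mouse feeder cells had been removed with magnetic beads, per the labels' protocols. Reads were aligned with BWA to the UMD3.1 assembly and peaks were called with MACS2, per the submitters' processing notes, which give no tool versions. The peak names point to the paired-end mode of MACS2, per the files. Peaks were called per library, per the files, which hold 1 list per library. Whether the inputs served as control in peak calling, which filters were applied and whether broad peaks were called is not given in the sources used here.

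The deposited score of each peak was read as the −log10 of a p or q value as MACS2 writes it, since its smallest value lay just above 2 in each list. Whether it is p or q is not given in the sources used here. The deposited positions (unit "other") are 1 base long, the summits of the peaks, so the lists hold no peak widths. A score moves with the depth of its library and was used in the comparisons to rank, filter and describe peaks within a list. The classes of H3K27me3 regions pool the scores of both lines, and the weighing of position-locked regions sets scores of several libraries side by side, where equal scores need not mean equal signal. The lists hold no read counts: the depth per library is unknown, and with it the power to call weak peaks, so a difference in the number of peaks between lines can come from depth.

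The tests fixed before the data were examined assumed peaks with a width. For 1-base summits, overlap by 1 base was replaced by a distance of at most 1000 bases, the Jaccard index in bases was left out, and covered bases per Mb were replaced by summits per Mb. Coordinates are in UMD3.1 as deposited, counted from 1. Summits on the 29 autosomes and the X were analysed, and those on unplaced sequences were counted apart. Summits per Mb used the span from base 1 to the last summit of any list on the chromosome, since no assembly of that build was used here.

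For each mark the percent of summits with a summit of the other line within 1000 bases was compared with 1000 circular shifts of one list within each chromosome, by at least 100000 bases (one-sided permutation test over positions, smallest p 0.001). The overlap of the marks within a line was tested in the same way, two-sided (smallest p 0.002). A second background used shifts of 20000 to 200000 bases. Scores of sites with and without the other mark were compared by permuting the label over sites 100000 times (two-sided, smallest p 1e-05). All these tests ask about genome positions within these libraries. None is a test across lines, since each line has 1 library per mark. Shares of sites carry 95% Wilson intervals, which cover counting error only.

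The rule for named regions, fixed before the data were examined, was the 10 widest regions shared by both lines for each mark. With summits only, regions were built by chaining the pooled summits of both lines up to 5000 bases apart, keeping those with at least 2 summits in each line, and width was the mean over lines of the distance from the first to the last summit. Position-locked regions, regions on autosomes with distances over 100 bases and regions of the X were added after the data were examined.

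Genes were not analysed here: no annotation or sequence of UMD3.1 was used, so promoter classes, the 16 gene lists fixed beforehand, distances to transcription starts and CpG content were not run. A gene table of the ARS-UCD2.0 assembly was not used, because coordinates of different assemblies cannot be mixed.

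The steps were tested on simulated lists. With 90.0% of 20807 summits planted as shared, as for H3K4me3 between lines, 90.2% were recovered, and with 56.9% of 23055 planted, in lists as long as those of H3K27me3 but with a lower share than observed, 57.6%. With none planted 1.42% were found, against 1.40% by shifts, and 2 of 40 unrelated pairs of shorter lists gave a p at or under 0.05. In these simulations summits were placed at random along the chromosomes, so lists as clustered as those of H3K27me3 were not covered. All 30 planted position-locked regions and all 30 planted loose regions were classed as planted. Alternatives covered the distance, summits above the median score of their list, merging of near summits, equal list lengths, autosomes alone, unplaced sequences, local shifts, each line alone, other chain gaps and the removal of position-locked regions. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.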

Results

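Trimethylation of histone H3 at lysine 4 (H3K4me3), a mark typical of active and poised promoters, and at lysine 27 (H3K27me3), the mark laid down by Polycomb repressive complexes, was profiled by ChIP-seq in bovine embryonic stem cells. These are primed pluripotent cells derived from blastocysts, and were grown on mouse feeder cells in medium with FGF2 and the WNT inhibitor IWR1. Both marks were profiled in line A and line B, which are independent lines, at passage 12. Each mark had 1 library per line (n = 2 per mark), so any difference between lines compares those libraries alone. The 2 input libraries were not analysed here. The lists give peak summits, each 1 base long, with a peak score, and hold no read counts, so the sequencing depth is unknown.

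H3K4me3 gave 20908 summits in line A and 21840 in line B. H3K27me3 gave 25225 summits in line A and 20684 in line B. H3K27me3 summits were clustered, with a median gap to the next summit of 3.16 kb in line A and 3.60 kb in line B, while H3K4me3 summits lay a median of 35.3 kb and 32.6 kb apart. Merging H3K27me3 summits within 5 kb of each other left 10238 on the placed chromosomes of line A, of 23055, and 8519 of 18755 in line B. The median peak score was 36.6 and 56.6 for H3K4me3 in lines A and B, and 9.31 and 9.49 for H3K27me3.

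The first comparison asked how far the independent lines carried each mark at the same places. H3K4me3 was largely shared. On the placed chromosomes, 93.6% of the summits of line A had a summit of line B within 1 kb, and 88.6% of those of line B had one of line A. H3K27me3 was shared less within 1 kb, at 64.3% of the summits of line A and 74.7% of those of line B. The gap between the marks depended on the distance. Pooled over lines, 59.1% of H3K27me3 summits were shared within 500 bases and 83.6% within 5 kb. For H3K4me3 these shares were 86.7% and 95.0%. Within 1 kb the H3K27me3 shares of lines A and B were 66.0% and 83.6% on autosomes, and 58.9% and 54.0% on the X chromosome. Without the regions called position-locked below, line A had 57.2% on autosomes and 57.8% on the X, and line B 77.7% and 52.9%.

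Both marks were shared far above chance. Pooled over lines, 91.0% of H3K4me3 summits were shared against 1.81% after circular shifts of whole chromosomes, 50.3 times as many, with a permutation p over positions of 0.001 (one-sided), the smallest that 1000 shifts can give. For H3K27me3 the pooled share was 69.0% against 2.55%, 27.1 times as many, with the same permutation p of 0.001. By part it was 73.5% on autosomes, 65.5 times chance, and 56.4% on the X, 8.60 times chance. Shifts of only 20 to 200 kb, which keep the local density of summits, gave 4.04% for H3K4me3 and 9.80% for H3K27me3, with 7.82% on autosomes and 15.3% on the X. Matching summits lay close together. In line A the median distance to the partner in line B was 54 bases for H3K4me3 and 84 bases for H3K27me3.

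Sharing rose with the peak score. For H3K4me3 in line A it rose from 64.3% in the lowest score decile to 99.7% in the highest, and in line B from 40.5% to 99.6%. For H3K27me3 it rose from 29.6% to 94.9% in line A and from 45.7% to 99.1% in line B. Summits of different marks were shared less than those of the same mark. The 4 pairs of an H3K4me3 with an H3K27me3 library shared 24.1% to 26.5% of their summits within 1 kb, whether or not the libraries came from the same line.

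**Figure D1:**
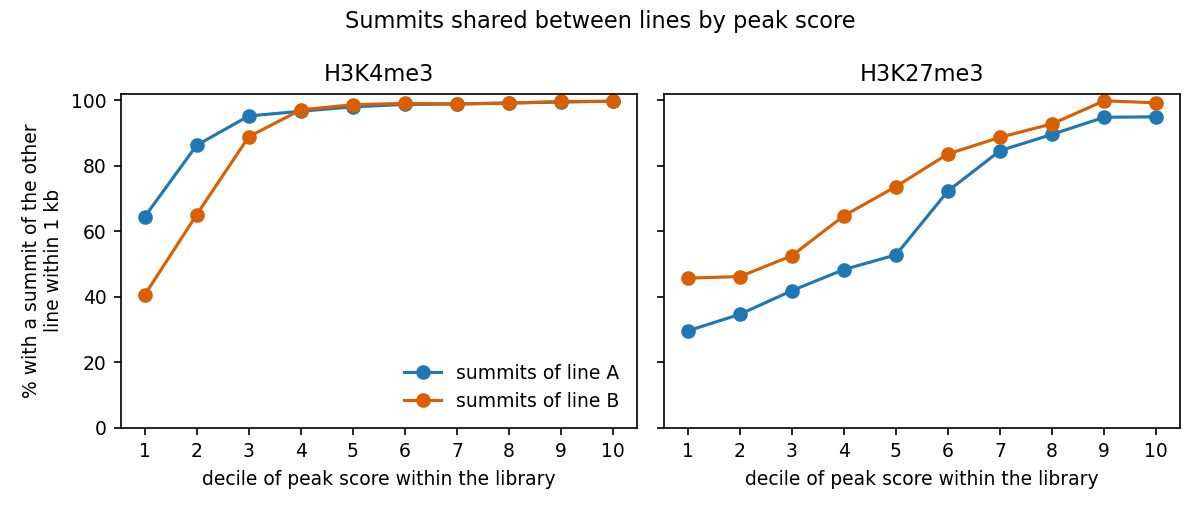
The percent of summits with a summit of the other line within 1 kb (y axis) is plotted by decile of the peak score within each library (x axis), for H3K4me3 on the left and H3K27me3 on the right, with 1 curve per line and 1 library per point. H3K4me3 is shared at 64.3% (line A) and 40.5% (line B) in the lowest decile and above 99% in the highest, while H3K27me3 starts at 29.6% and 45.7%.

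The broadest H3K4me3 regions were defined by chaining summits up to 5 kb apart. The broadest, on chromosome 25 at 2593880 to 2637919 (UMD3.1), spanned a mean of 41.6 kb per line, with 12 summits in line A and 16 in line B, and held H3K27me3 summits too, 15 and 14. The next, on chromosome 29 at 19410119 to 19448738, spanned 38.2 kb with 18 and 12 H3K4me3 summits and 26 and 22 H3K27me3 summits. On chromosome 27 the regions at 26337044 to 26368237 and 23690913 to 23717887 stood out by their scores, with medians of 865 and 589 in line A, against a median of 36.6 over all summits of that library. The region on chromosome 4 at 103642685 to 103663703 had a median score of 524 in line A. In the regions on chromosomes 27, 4 and 29 the summits of the lines lay at nearly the same bases. The median distance between lines was 12 and 6 bases on chromosome 27, 4 on chromosome 4 and 15 on chromosome 29, as in the position-locked H3K27me3 regions described below. The other 5 of the 10 broadest were at 53501863 to 53524917, 50173336 to 50190189 and 62701815 to 62718258 on chromosome 18, at 30900157 to 30925564 on chromosome 23 and at 48206548 to 48224106 on chromosome 21, spanning 16.4 to 22.7 kb. H3K27me3 summits of both lines lay in or within 1 kb of each of the 10. What genes lie at these positions was not analysed here.

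The broadest H3K27me3 regions were far longer. The longest, on chromosome 27 at 28556165 to 28939537, spanned 383 kb with 292 summits in line A and 259 in line B. It was followed by regions on chromosome 8 at 74485090 to 74804365 (319 kb), chromosome 3 at 82708041 to 82912208 (204 kb), chromosome 29 at 30225285 to 30386289 (161 kb) and chromosome 1 at 145293955 to 145452212 (158 kb). The other 5 of the 10 broadest were at 56714301 to 56855304 and 110659924 to 110762643 on chromosome 8, at 114106284 to 114241584 on chromosome 5, and at 32374003 to 32472521 and 30275173 to 30371377 on chromosome 25. In 9 of these 10 regions the summits of the lines lay at nearly the same bases, with a median distance between lines of 5 to 17 bases, against 51 bases in the region of chromosome 25 that starts at 32374003.

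Of 545 H3K27me3 regions with at least 5 summits in each line, 398 were on autosomes and 147 on the X. In 165 of them the median distance between lines was at most 30 bases, a limit chosen after the values were seen, and these are called position-locked below. They covered 5.55 Mb, held 18.5% of the placed H3K27me3 summits of line A and 20.0% of those of line B, and had a median score of 128. In 320 other regions the distance was over 100 bases, with a median score of 7.77. Of the 215 such regions on autosomes, 173 (80.5%) also had H3K4me3 summits of both lines in them or within 1 kb, while 20 of the 105 on the X did. The widest on autosomes, also chosen after the values were seen, were at 2589210 to 2675654 on chromosome 25 (82.5 kb), around the broadest H3K4me3 region, at 69341100 to 69413727 on chromosome 4 (68.7 kb), with a neighbour at 69272098 to 69311067 (36.6 kb), and at 38544455 to 38605570 on chromosome 19 (56.3 kb).

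**Figure D2:**
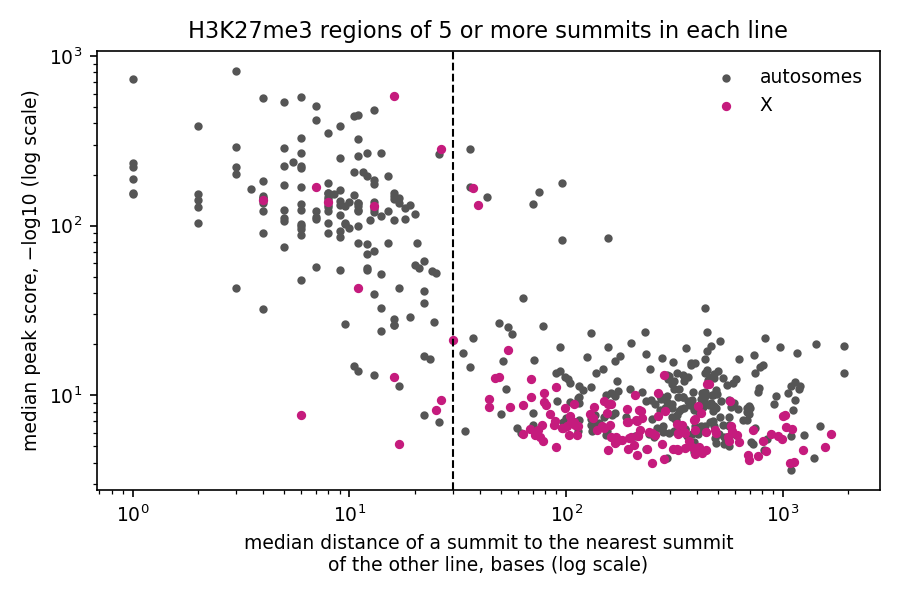
Each point is an H3K27me3 region with at least 5 summits in each line, plotted by the median distance of its summits to the nearest summit of the other line in bases (x axis, log scale) and its median peak score (y axis, log scale), with autosomal regions in grey and regions of the X in pink. The 165 regions left of the dashed line at 30 bases have a median score of 128, and the 320 regions beyond 100 bases one of 7.77.

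The second comparison asked where both marks lay together, as at the bivalent promoters of developmental genes in pluripotent cells. Each mark came from its own library of many cells. Summits close together therefore need not lie on the same molecule, the same copy of a chromosome or in the same cell. Whether the sites are promoters was not analysed here. A minority of H3K4me3 sites carried H3K27me3. In line A 5447 of 20807 placed H3K4me3 summits (26.2%) had an H3K27me3 summit within 1 kb, and in line B 4700 of 21794 (21.6%). The share was larger on the X, at 606 of 841 summits (72.1%) in line A and 552 of 833 (66.3%) in line B, than on autosomes, at 24.2% and 19.8%. Seen from H3K27me3, 31.1% and 34.0% of the autosomal summits had H3K4me3 within 1 kb, against 12.5% and 10.6% of those on the X.

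The overlap exceeded chance 17.6 times in line A (1.49% after circular shifts) and 18.2 times in line B (1.18%), with a permutation p over positions of 0.002 in each line (two-sided), the smallest that the shifts can give. Shifts of 20 to 200 kb gave a higher background, 2.81% in line A and 2.11% in line B. On the X, where circular shifts gave 6.28% and 6.84%, the overlap was 11.5 and 9.68 times chance. On autosomes, where they gave 1.29% and 0.965%, it was 18.8 and 20.5 times chance. The higher chance share caps the fold on the X, so the folds do not rank the parts. The marks met closely: 14.2% of the H3K4me3 summits of line A lay within 250 bases of an H3K27me3 summit, against 0.387% by chance, and 10.8% of those of line B, against 0.286%. Among summits above the median score of their list the mean overlap of the lines was 8.06%, against 23.9% with all summits, and that on the X 41.1%, against 69.2%.

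Of 19472 H3K4me3 summits of line A shared with line B, 3540 had H3K27me3 in both lines (18.2%, 95% Wilson interval 17.6% to 18.7%), 1363 in line A alone, 554 in line B alone and 14015 in neither (72.0%). On the X 453 of 760 shared H3K4me3 sites had H3K27me3 in both lines (59.6%, Wilson interval 56.1% to 63.0%) and 143 in neither (18.8%). On autosomes 3087 of 18712 did (16.5%). These intervals cover counting error only, and sites are not independent replicates. With only the summits above the median score of their list, 443 sites had both marks in both lines.

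H3K4me3 was weaker where H3K27me3 was present. On autosomes the median H3K4me3 score in line A was 22.4 at the 4841 summits with H3K27me3 and 46.2 at the 15125 without, and in line B 34.9 at 4148 and 70.4 at 16813. The permutation p over sites (two-sided) was 1e-05 in each line, the smallest that 100000 resamples can give. The mean log2 ratio of the lines was -1.03 with all summits and -0.40 among summits above the median score of their list. The share with H3K27me3 was highest in the weaker deciles of H3K4me3 score, at 36.9% in the third decile of line A and 30.4% in the fourth of line B, and fell to 7.41% and 4.82% in the highest. The reverse relation had no fixed direction. The median H3K27me3 score with and without H3K4me3 was 11.8 and 11.1 in line A, at the edge of the threshold of 0.05 (permutation p = 0.0486 with 100000 resamples and 0.052 with 2000), and 9.93 and 21.2 in line B (permutation p = 1e-05), while without the position-locked regions it was higher with H3K4me3 in both lines, at 10.4 against 6.49 and 9.59 against 7.30.

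**Figure D3:**
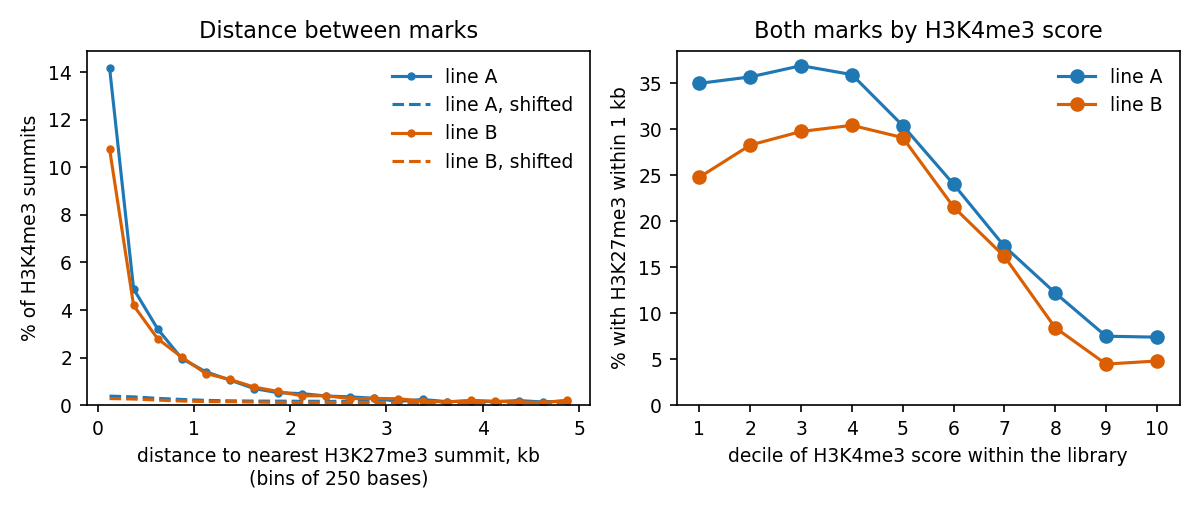
On the left, the percent of H3K4me3 summits (y axis) is plotted by distance to the nearest H3K27me3 summit in kb, in bins of 250 bases (x axis), for each line, with dashed lines for the mean of the circular shifts. On the right, the percent of autosomal H3K4me3 summits with H3K27me3 within 1 kb (y axis) is plotted by decile of H3K4me3 score (x axis), and falls to 7.41% in line A and 4.82% in line B in the highest decile.

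The third comparison described how the marks were spread over the chromosomes. H3K27me3 was concentrated on the X. The X held 23.4% of the placed H3K27me3 summits of line A (Wilson interval 22.8% to 23.9%) and 30.2% of those of line B (29.6% to 30.9%), but 4.04% and 3.82% of the H3K4me3 summits. Per Mb, the X had 36.2 and 38.1 H3K27me3 summits in lines A and B, against 6.53 and 4.65 on the median autosome, a ratio of 6.87 ± 1.87 (SD, n = 2). It ranked first of 30 chromosomes in both lines, and had 2.14 and 2.95 times the density of the next, chromosome 27.

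For H3K4me3 the X ranked 24 of 30 in both lines, with 5.65 and 5.60 summits per Mb and a ratio to the median autosome of 0.686 ± 0.0219 (SD, n = 2). H3K4me3 was densest on chromosomes 18 (18.3 and 20.1 per Mb), 19 (18.2 and 19.7) and 25 (17.0 and 17.5), and sparsest on chromosome 20 (4.51 and 4.71). H3K27me3 was sparsest on chromosome 12 (3.64 and 2.78). The H3K27me3 summits of the X were weak, with a median score of 5.45 in line A and 5.32 in line B against 11.4 and 13.2 on autosomes. Among summits above the median score of their list the H3K27me3 ratio of the X was 2.69 and the H3K4me3 ratio 0.212.

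Across the 29 autosomes the density of H3K4me3 in line A followed that in line B (Pearson r = 0.997, Spearman rho = 0.993, permutation p = 1e-05 for both, adjusted p = 2e-05), and so did that of H3K27me3 (r = 0.985, rho = 0.985, permutation p = 1e-05, adjusted p = 2e-05). Without the 2 autosomes farthest from the median these were r = 0.996 and r = 0.973. Autosomes rich in H3K4me3 were also richer in H3K27me3. In line A r was 0.656 (permutation p = 0.0006, adjusted p = 0.0008) and rho 0.633 (permutation p = 0.0004, adjusted p = 0.0005), and in line B r was 0.531 (permutation p = 0.005, adjusted p = 0.005) and rho 0.528 (permutation p = 0.004, adjusted p = 0.004). Adjustment was by Benjamini-Hochberg over the 4 relations. Without chromosomes 18 and 19 r was 0.542 and 0.411. The mean r of the lines, 0.594, was 0.327 among summits above the median score of their list (permutation p = 0.12, the higher of the lines) and 0.895 without the position-locked regions. Chromosomes of 1 genome are not independent replicates.

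**Figure D4:**
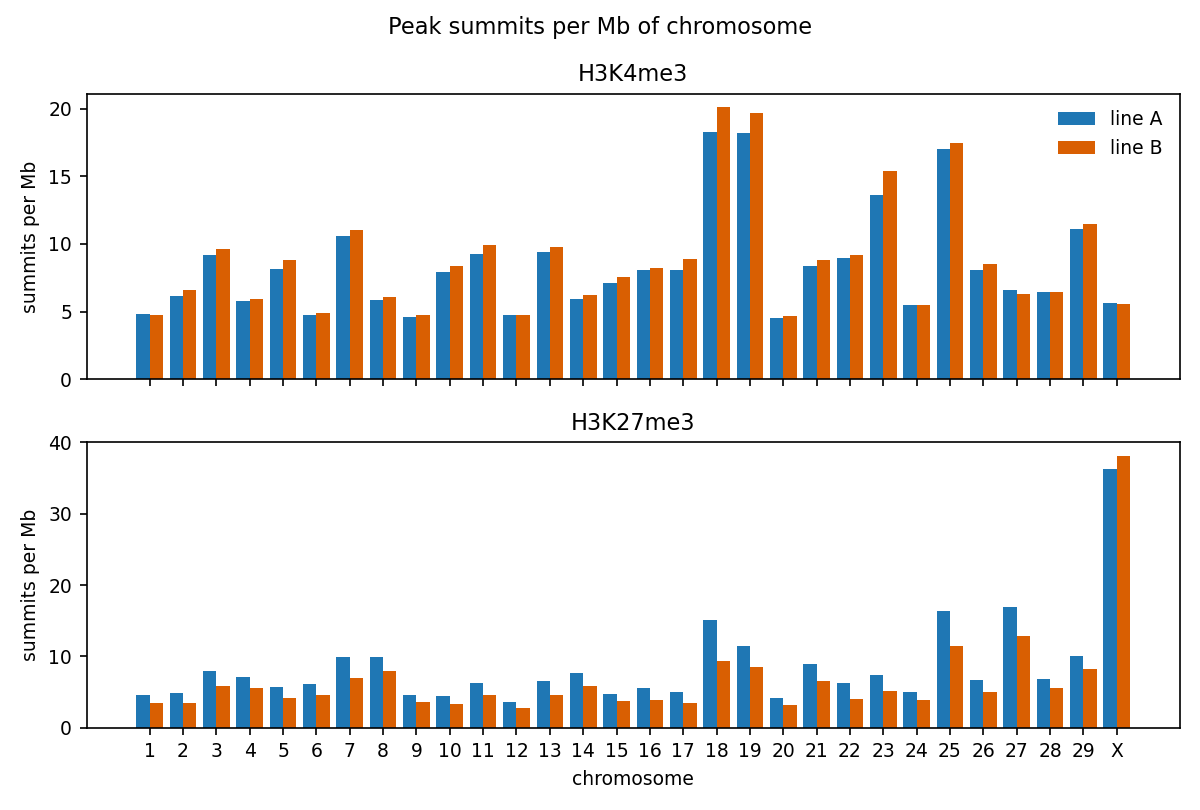
Bars give the peak summits per Mb (y axis, from 0) on each chromosome (x axis) for H3K4me3 above and H3K27me3 below, with 1 bar per line and 1 library per bar. The H3K27me3 bars of the X reach 36.2 in line A and 38.1 in line B, against 16.9 and 12.9 on chromosome 27.

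The excess of H3K27me3 ran along all windows of the X. The last full window ended at base 145000000, so the end of the X, up to 148.8 Mb, was not covered. In windows of 5 Mb, all 29 windows of the X lay above the median autosomal window in both lines, which held 21 summits in line A and 16 in line B. The windows of the X held a median of 170 and 164 summits, and the lowest 50 and 57. The highest window, at 35 to 40 Mb, held 714 summits in line A and 694 in line B, with 41 and 40 H3K4me3 summits. The widest H3K27me3 region of the X lay in it, at 37234906 to 37321063, with 43 summits in each line and no H3K4me3 summit. The profile of the X was alike in the lines (r = 0.988 across windows, which are not independent replicates). For H3K4me3, 13 of the 29 windows lay above the autosomal median in each line.

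**Figure D5:**
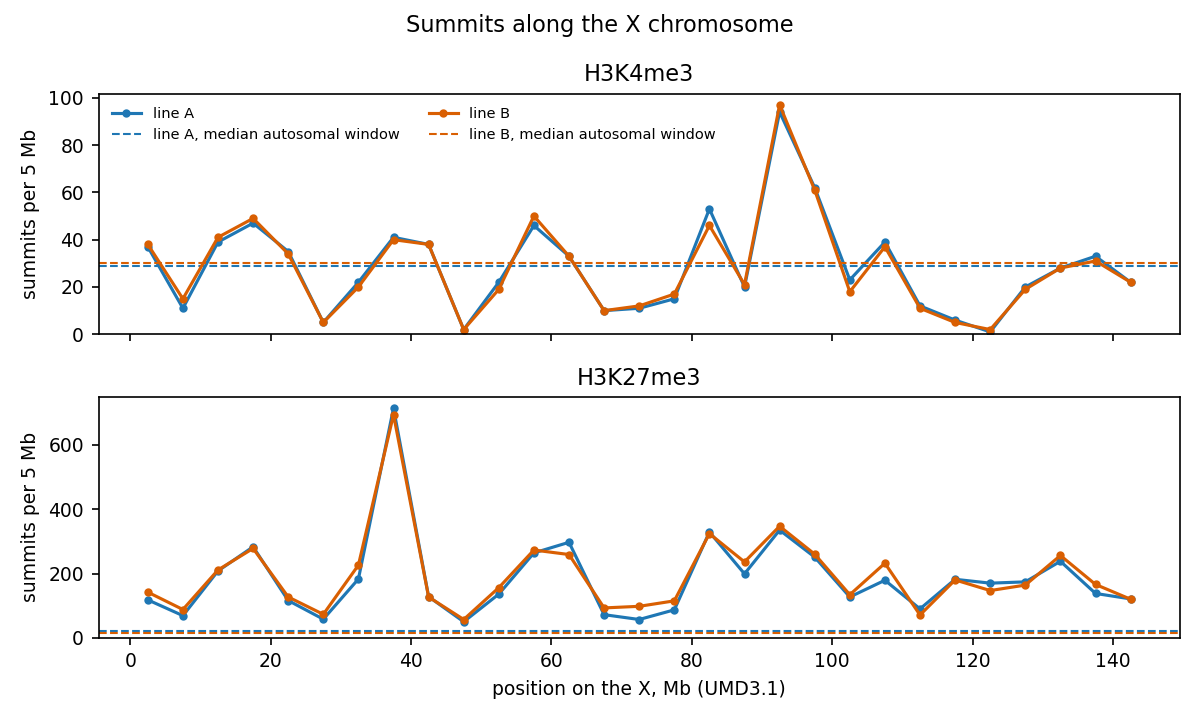
Summits per window of 5 Mb (y axis) are plotted by position on the X in Mb (x axis, UMD3.1) for H3K4me3 above and H3K27me3 below, with 1 curve per line and dashed lines for the median autosomal window. H3K27me3 lies above its dashed lines in all 29 windows and peaks at 714 and 694 summits between 35 and 40 Mb.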

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

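Summits on unplaced sequences of the assembly, which enter no comparison above, drew attention as signal outside the main measurement, judged without a control list. H3K27me3 had 2170 such summits in line A (8.60% of its list) and 1929 in line B (9.33%), on 1272 and 1259 sequences, and 1205 sequences carried it in both lines. H3K4me3 had 101 in line A and 46 in line B, on 89 and 37 sequences. The H3K27me3 summits there had a median score of 26.4 in line A and 29.5 in line B, above the medians of 11.4 and 13.2 on autosomes. Of those in line A 1952 had a summit of line B within 1 kb, at a median distance of 21 bases, and of those in line B 1786 had one of line A. Of the 1205 sequences, 19 had H3K4me3 in both lines.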

How the results depend on the processing

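Tried after seeing the data were other distances (500 bases, 2 kb and 5 kb), removal of position-locked regions, merging within 5 kb, other chain gaps, local shifts and unplaced sequences. Of 108 alternatives, 94 kept the direction and the side of the threshold or, with no test, stayed within 1.5 times of a count or 1 SD between lines of another value, 10 moved further without reversing, 1 lost its call and 3 reversed. Some of the 94 were fixed in advance. With 1 line left out, an X ratio could not move past 1 SD between lines. Nor could a test of the overlap of the marks, their scores or their correlation lose its call, since its main p was the higher of the lines. Sharing between lines ranged from 86.7% to 95.0% for H3K4me3 and from 59.1% to 83.6% for H3K27me3. Among summits above the median score of their list the sites with both marks in both lines numbered 443, against 3540, the ratio of the X to the median autosome was 0.212 for H3K4me3 and 2.69 for H3K27me3, and 236 H3K27me3 regions had at least 5 summits in each line, against 545. Fewer summits entered these values by construction. The mean correlation of the marks across autosomes there was 0.327 (permutation p = 0.12, the higher of the lines), against 0.594. Merging within 5 kb gave X ratios of 0.658 and 8.92, and 10238 and 8519 H3K27me3 summits in lines A and B. Without position-locked regions the H3K27me3 ratio of the X was 9.08. With either line alone, sites with both marks numbered 4700 to 5447, since the other line was not required. The log2 ratio of H3K27me3 score with over without H3K4me3 in line A was 0.10 with all summits, -1.15 above the median score and -0.48 with the longer list shortened to the other, and 0.31 after merging within 1 kb and 0.67 without position-locked regions. In line B it was -1.09, and 0.39 without those regions. The cause was not tested. Not run were overlap by part of a peak and covered bases (no widths), the median score for peak counts (fixed by construction), and every promoter, start and CpG alternative. No paired analysis was possible because no result comes from a test across samples. Depth is unknown, so how far it limits the weaker peaks could not be measured.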

Other observations

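The libraries of the lines differed in H3K27me3 on autosomes but not in the same direction on the X. Line A had 1.35 times the autosomal H3K27me3 summits of line B, with a higher density on all 29 autosomes, and 0.950 times those on the X. For H3K4me3 line A was denser on 3 of 29 autosomes. H3K27me3 summits with none of the other line within 10 kb numbered 3802 in line A (16.5%) and 1685 in line B (8.98%), with 21.6% and 61.1% of them on the X. Those for H3K4me3 numbered 553 (2.66%) and 1140 (5.23%). Most were weak, with median scores of 4.77 and 4.41 for H3K27me3 and 4.75 and 8.24 for H3K4me3. The strongest H3K27me3 summit of line A of this kind was at 14673208 on chromosome 26 (score 1053), and that of line B at 38497819 on chromosome 19 (score 28.4). For H3K4me3 they were at 41490659 on chromosome 4 in line A (42.7), inside a position-locked H3K27me3 region like 6 of the 10 strongest of this kind in line A, and at 103845730 on chromosome 4 in line B (132). Near the latter, at 103846366, line A had an H3K27me3 summit of score 455 with none of line B within 10 kb. These differences between single libraries were not tested.

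Of the tests below, those of merged summits and of strong regions had their predictions written before the values were seen, and all others were chosen after. A first test of copy number on the X, the share of its H3K27me3 summits in position-locked regions (2.84% in line A and 2.49% in line B), was replaced by a test of scores because what those regions are stayed open. First tests at the strongest H3K4me3 summits restated the pattern and were replaced by a test of H3K27me3 scores.

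H3K27me3 summits were denser on the X than on autosomes. Splitting of broad domains into summits up to 5 kb apart is argued against by the ratio after merging within 5 kb, 8.92. Splitting into summits farther apart was not tested. For more copies of X sequence in the cells than in the assembly, the test was the H3K27me3 score. Its median on the X was at most 0.713 times that on autosomes with position-locked regions left out. That decides nothing, because the median covers called summits only and falls when more weak sites pass the calling threshold. More DNA or better mapping on the X was examined by H3K4me3, whose median score on the X was at most 0.453 times that on autosomes. That decides nothing either, because H3K4me3 was weaker on autosomes too where H3K27me3 was present. Of the H3K4me3 summits of the X, 72.1% in line A and 66.3% in line B had H3K27me3 within 1 kb. Chromosome-wide H3K27me3, as on an inactive X, may account for it as a hypothesis: it needs the excess to run along the whole X. In both lines 29 of 29 windows lay above the autosomal median, a count that other chromosome-wide causes would give too. Of these windows, 22 in line A and 26 in line B lay above the 95th percentile of autosomal windows. The windows ended at base 145000000, so the end of the X was left out of this count. The sex of the lines is not in the labels and the inputs were not analysed here, so this stays open.

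In position-locked H3K27me3 regions the summits of independent lines lay a median of 9.5 bases apart. Sequence present in more copies in the cells than in the assembly could give such positions, but H3K4me3, at least 3.60 times as dense inside these regions as outside, decides nothing, because it was denser still in regions over 100 bases apart (107 per Mb in line B, against 29.3 in the position-locked regions of that line, and also higher in line A). The H3K4me3 summits inside position-locked regions were weak, with a median score of 9.20 in line A and 17.9 in line B, against 37.6 and 57.1 outside. Of them, 41.1% in line A and 92.1% in line B were shared with the other line. Ordinary, strongly marked domains predicted summits over 100 bases apart in many equally strong regions, and 0 of 91 had them, but 83 of the 91 were position-locked themselves and only the other 8, at 36 to 96 bases, bear on it. The prediction also took the distance not to depend on score, but in line A it fell as the H3K27me3 score rose. Outside the H3K27me3 regions with at least 5 summits in each line it was 262 bases at scores of 2 to 5. It was 115 at 20 to 50, 12.5 at 50 to 100 and 9 at 100 to 200. For H3K4me3 of line A outside position-locked regions it was 46 and 44 bases in the last score ranges. In 5 position-locked H3K4me3 regions of median score 641 it was 12 bases, but these were selected by distance, so that value does not bear on the score. Scores are not on 1 scale across libraries, and the drop past a score of 50 for H3K27me3 may itself belong to the pattern, so the explanations cannot be told apart here, where the inputs were not analysed.

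A minority of the strongest H3K4me3 summits coincided closely with H3K27me3 summits in both lines. In the top 0.5% by score, 30.5% (line A) and 33.0% (line B) had a summit of each other library within 100 bases, against 0.558% and 0.483% in the rest of the top 10%, and 25 of 105 and 27 of 109 lay on chromosome 27. These values count summits, not separate loci. The position-locked H3K4me3 regions of chromosome 27 held 15 and 13 summits in line A, with median scores of 865 and 589. The lowest score of the top 0.5% there was 157. How many separate loci the coinciding summits form was not counted. At the coinciding top summits the median H3K27me3 score was 134 times that at the other coinciding H3K4me3 summits of the same library in line A. In line B it was 11.7 times, so the size of the gap differed widely between the libraries. Both values argue against sites with both marks like those at other H3K4me3 strengths. Sequence present in more copies in the cells than in the assembly may account for it, since copies would raise both marks, but other causes of coinciding signal were not tested and the inputs were not analysed here.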
